A study of Mus musculus with 2 samples.

How the data were processed

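C/EBPα ChIP-seq was carried out on primary mouse B cells with an antibody to C/EBPα, in 1 untreated sample and 1 sample treated with estradiol for 18 h. Groups were taken from the treatment labels. The peak list recorded for the sample labelled with estradiol, a BED file of 6 columns without a header, was analysed. Its name carries the abbreviation EOH, which the labels do not explain and which could stand for a vehicle; the label was followed. The untreated sample was not analysed here. The submitters' processing notes name Bowtie2 2.1.0, SAMtools, HOMER 4.3 and the build mm9, without saying which step used which tool. The calling threshold, the control used for calling, the read totals and any later filter are not given in the sources used here. The deposited list holds the authors' score for each peak, whose definition and normalization are not given in the sources used here, and its values are 0.5 or whole numbers from 1 to 10. It was used only to describe and filter peaks within this list.

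The build was checked against chromosome lengths of mm9 and mm10 held in GenomeInfoDb 1.38.1 (R 4.3.3). Every peak ended inside its mm9 chromosome, while 8 peaks on 2 chromosomes (7 on chromosome 7 and 1 on chromosome 12) ended past the mm10 length. The gene table used here is on GRCm38, the assembly behind mm10, so no peak was assigned to a gene and no coordinate was converted. For want of the mm9 genome sequence, the tests of 15 sequence patterns, the C/EBP motif among them, and of motif share by score were not run. Nor were those of distance to transcription start sites and of 11 gene lists, for want of a gene table on mm9. Those lists were myeloid, B-lineage, T and NK cell, erythroid and megakaryocyte markers, pluripotency genes, DNA methylation and chromatin regulators, epithelial-mesenchymal transition genes, myeloid and stress transcription factors, hepatocyte and adipocyte genes, stromal feeder genes, and signalling and survival genes. They have no result here.

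BED starts were raised by 1 so that positions count from 1. Peak density was the number of peaks per Mb of mm9 length past the first 3 Mb of each chromosome, an unsequenced stretch at the start of mouse chromosomes; the lowest peak start was 3204914. Density intervals are 95% exact Poisson intervals, and ratios of densities have exact conditional binomial intervals. Chromosome counts were tested against length shares with two-sided exact binomial tests and Benjamini-Hochberg adjustment over 20 chromosomes. These tests treat peaks as independent, so counts of clusters were an alternative. Spacing was compared with 1000 random placements of the peaks on their own chromosomes (fixed seed), with two-sided permutation p-values. Clusters were runs of peaks whose neighbouring centres lay within 50 kb. Differences of means between sets of peaks were tested with 100000 permutations, and rank correlations, and the comparison of scores within 10 parts of the list, with 10000. The intervals and tests cover the sampling of peaks in 1 library, not variation between cultures or animals. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

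Peaks were named in the text by a rule set before the data were examined, as were the spacing test with its distances and the filter on score. The rule names the 10 peaks with the highest score where genes cannot be assigned. Ties were broken by list position, which was chosen after seeing the data. The tests by chromosome, the clusters, the list order and the serial numbers were chosen after seeing the data. Alternatives were other neighbour distances, the 894 peaks with a score of 3 or more, the first 834 peaks of the list, other ranges of random placement, clusters counted once, and whole chromosome lengths.

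The tests were tried on simulated data, 100 sets of 1669 peaks each. The spacing test called 2 of 100 sets placed at random and 100 of 100 sets in which 50 peaks were moved to lie beside another. The chromosome test called any chromosome in 4 of 100 sets drawn by length alone, and called X in 100 of 100 sets in which the density on X was multiplied by 0.5. The simulated counts treated peaks as independent, so the rate of false calls among clustered peaks was not measured.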

Results

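C/EBPα is a basic leucine zipper transcription factor of the myeloid lineage. The study asked where it occupies the genome of primary mouse B cells after 18 h of estradiol, in comparison with cells given no estradiol. The B cells were CD19-positive pro-B and pre-B cells from bone marrow, grown with IL-7, a cytokine that early B cells need. C/EBPα-bound chromatin was measured by ChIP-seq, in which DNA fragments pulled down by an antibody are sequenced and regions with an excess of reads are called as peaks. The series holds 2 samples, 1 untreated and 1 treated with estradiol for 18 h, and so 1 sample per group. The peak list analysed here is the one recorded for the estradiol sample, and the untreated sample was not analysed here, so the change on treatment and the background in untreated cells were not measured. The list's own name carries the abbreviation EOH, which the labels do not explain and which could also stand for a vehicle. Values are given for the estradiol sample as labelled, and the list itself gives no means of telling these readings apart. Nothing below separates peaks that appeared with estradiol from peaks that were there before it. With 1 library there was no replicate check, and every interval and p-value describes the spread of peaks in this list. Read totals are not given in the sources used here, so the sequencing depth behind the peaks is unknown.

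The list of the sample labelled as 18 h of estradiol held 1669 C/EBPα peaks. Peaks lay on each of the 19 autosomes, with 1643 peaks in all, and on the X chromosome, with 26. Every peak was 278 bp wide, and together they covered 464 kb, or 0.0176% of these chromosomes in the mouse build mm9. All coordinates are mm9 and count from 1. Genes at the peaks were not assigned, because the gene table used here is on another build.

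**Figure D1:**
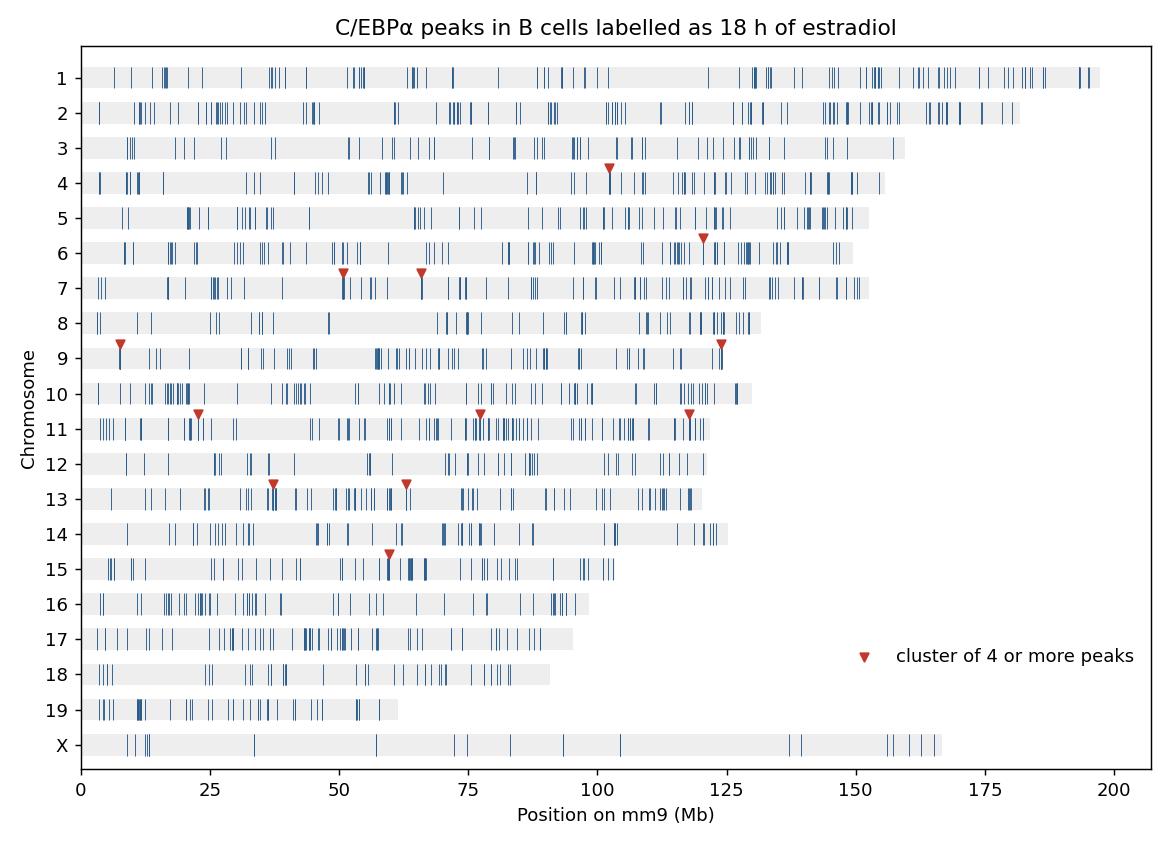
Positions of the 1669 C/EBPα peaks (blue lines) of the estradiol sample along each chromosome (grey bars, vertical axis), with position on mm9 in Mb on the horizontal axis. Red triangles mark the 12 clusters of 4 or more peaks, of which 3 lie on chromosome 11 and none on X.

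C/EBPα peaks were unevenly spread over the chromosomes. Chromosome X carried 0.159 peaks per Mb (95% exact Poisson interval 0.104 to 0.233), against 0.680 over the autosomes, a ratio of 0.234 (95% exact interval 0.152 to 0.343). X makes up 6.35% of the analysed length and held 1.56% of the peaks. Chromosome 11 was the densest, with 133 peaks or 1.12 per Mb (0.937 to 1.33), which was 1.70 times the density of the other autosomes (1.41 to 2.03). Chromosome 2 carried 148 peaks where its length share would give 116, and chromosome 3 carried 71 where its length share would give 101. Densities on the autosomes ranged from 0.453 per Mb on chromosome 3 to 1.12 on chromosome 11, with a median of 0.689.

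Each chromosome's count was set against its share of the length in a two-sided exact binomial test with Benjamini-Hochberg adjustment over the 20 chromosomes. Of these, 2 carried more peaks than their length share (exact binomial test, adjusted p = 2.0e-08 for chromosome 11 and 0.014 for chromosome 2) and 2 carried fewer (adjusted p = 8.0e-20 for X and 0.0097 for chromosome 3). The other 16 chromosomes did not pass the adjusted threshold of 0.05, and 3 of them had an unadjusted p below it. The calls for chromosomes 2 and 3 were lost among the first 834 peaks of the list (exact binomial test, adjusted p = 0.33 and 0.068), with counts of 1.19 and 0.671 times the length share there, against 1.28 and 0.701 times in the whole list. That for chromosome 2 was also lost when peaks within 50 kb of each other were counted once (1.252 times, exact binomial test, adjusted p = 0.065).

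**Figure D2:**
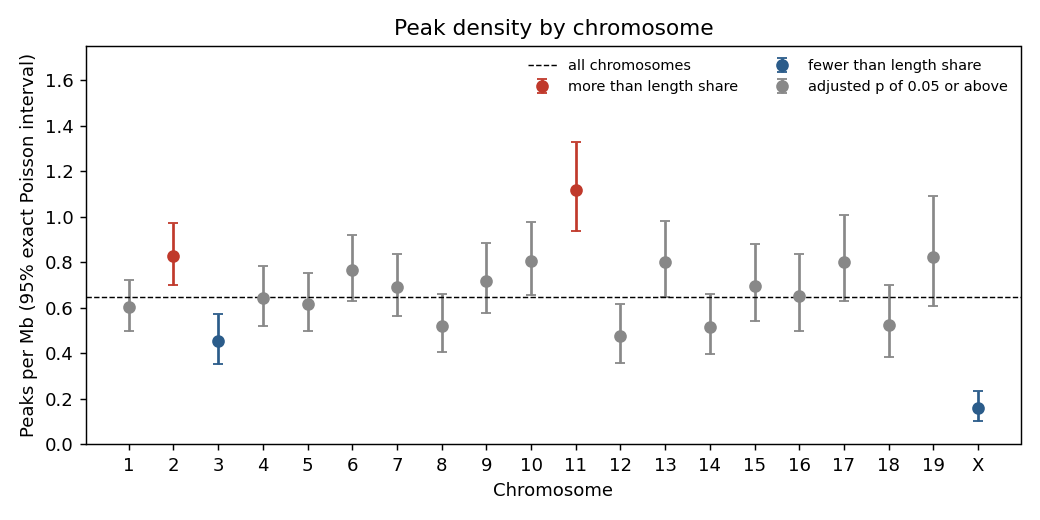
C/EBPα peaks per Mb (vertical axis) for each chromosome (horizontal axis), with 95% exact Poisson intervals; the dashed line is the density over all chromosomes. Chromosome X stands at 0.159 and chromosome 11 at 1.12 peaks per Mb; colours mark chromosomes above (red) or below (blue) their length share at an adjusted p under 0.05.

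C/EBPα peaks lay close together. Of the 1669 peaks, 184 (11.02%) had another peak within 10 kb, where random placement of the same number of peaks on each chromosome gave 1.41% ± 0.416 (SD over 1000 placements), an excess of 7.82 times. Placements in which each peak moved by at most 500 kb, which keep differences in density between much wider regions, gave 3.07% ± 0.592, an excess of 3.59 times. The median distance between neighbouring peaks was 513 kb, against 997 ± 26.7 kb for random placements. Peaks joined at distances of up to 50 kb formed 44 clusters of 3 or more peaks, where random placements gave 2.00 ± 1.37, and 12 clusters of 4 or more, where no random placement gave above 2. In two-sided permutation tests each of these differences had p = 0.002, the smallest that 1000 placements can give. The median distance, the clusters and the longest intervals given below were set only against placement along the whole analysed chromosome. Their differences from random may therefore include differences in density between wider regions.

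The most populated cluster held 6 peaks on chromosome 13, from 37148626 to 37222836, a span of 74.2 kb. Clusters of 5 peaks lay on chromosome 9 (7551988 to 7593751), chromosome 7 (65930080 to 65986506) and chromosome 11 (22714074 to 22797588). Of the 8 clusters with 4 peaks, the most compact spanned 24.5 kb on chromosome 7 (50785743 to 50810230) and 24.9 kb on chromosome 6 (120404689 to 120429538). Chromosome 11 held a further 2 of them, at 77185786 to 77256703 and 117797075 to 117848792. Chromosome 9 held another at 123952679 to 123987360 and chromosome 13 another at 62981423 to 63054330. The last 2 were on chromosome 4 (102296892 to 102358026) and chromosome 15 (59559746 to 59662989). At the other end, the longest autosomal interval without a peak was 20.9 Mb on chromosome 8, between 47971654 and 68910084. Random placements gave a longest autosomal interval of 12.8 ± 2.22 Mb (two-sided permutation p = 0.018). On X the longest interval was 32.6 Mb, between 104446103 and 137041530, and it was not distinguishable from the 23.0 ± 6.12 Mb that the same 26 peaks gave at random (permutation p = 0.15).

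The list gives each peak a score of the authors' own, which was 0.5 or a whole number from 1 to 10. Its meaning is not given in the sources used here, so it is not read as binding strength. The mean score was 2.79 ± 1.59 (SD over 1669 peaks), 449 peaks (26.9%) had a score of 3, and 98 peaks (5.87%) had 0.5. Just 5 peaks had a score of 10. These lay on chromosome 13 (24691595 to 24691872), chromosome 7 (146111280 to 146111557), chromosome 10 (94537739 to 94538016), chromosome 9 (64638579 to 64638856) and chromosome 16 (92715697 to 92715974), and none of them had another peak within 100 kb. A score of 9 was given to the peaks on chromosome 10 at 120925751 to 120926028, which had a neighbour 5.28 kb away, and on chromosome 1 at 90484078 to 90484355. Of the 7 peaks with a score of 8, the 3 that stood earliest in the list were on chromosome 11 (51885444 to 51885721), chromosome 1 (182779083 to 182779360) and chromosome 12 (74880342 to 74880619).

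The score fell along the list, with a Spearman rho of -0.35 between score and list position (95% bootstrap interval -0.40 to -0.31; Pearson r = -0.40; permutation p = 0.0001, the smallest that 10000 permutations can give). This is a relation across peaks of 1 library, and peaks are not independent replicates. The first 166 peaks averaged 4.04 ± 2.25 (SD over peaks) and the last 167 averaged 2.07 ± 0.848. Even so, the first peak of the list, on chromosome 2 at 45135034 to 45135311, had the lowest score, 0.5. The peaks in the 4 positions after it scored 3, 2, 3 and 5, and lay on chromosome 18 (55006145 to 55006422), chromosome 4 (116793016 to 116793293), chromosome 2 (170147507 to 170147784) and chromosome 5 (105387391 to 105387668). These first 5 peaks were chosen for mention after their scores were seen. Peaks with a neighbour within 10 kb had a mean score of 3.06 ± 1.67 (184 peaks), against 2.76 ± 1.57 for the other 1485 (two-sided permutation p = 0.015). Both quantities fell along the list, the share with a neighbour being 13.9% among the first 166 peaks and 5.99% among the last 167. Compared within 10 successive parts of the list, the mean scores differed by 0.122 (two-sided permutation p = 0.32). Peaks on X had a mean score of 2.23 ± 1.30 (26 peaks), against 2.80 ± 1.59 on the autosomes (two-sided permutation p = 0.069), which did not pass the threshold of 0.05.

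Peak names carry a serial number within each chromosome. The highest numbers seen add up to 2875 over the 20 chromosomes, and the 1669 peaks make up 58.1% of these numbers (95% Wilson interval 56.2% to 59.8%). Numbers above the highest seen cannot be counted, so 58.1% may be too high as a share of all numbers given. The interval takes 2875 as known. Why the other numbers do not occur in the list is not given in the sources used here. Within chromosomes the numbers ran nearly in list order, with Spearman rho between 0.97 and 0.99. The share of numbers seen in the list was lower among high numbers, though it did not fall at every step. When each chromosome's numbers were parted into 10 equal ranges, it was 77.1% (71.9% to 81.6%) for the lowest 284 numbers and 83.2% (78.5% to 87.1%), the highest value, for the next 292. It was 35.9% (30.6% to 41.5%), the lowest value, in the range before the last and 37.4% (32.0% to 43.2%) for the highest 286 numbers. The last range holds the highest number seen on each of the 20 chromosomes, which is in the list by definition. This raises its share, so the small rise at the last step is not read as a result. These shares pool the 20 chromosomes. On chromosome 11 nearly all of the lowest numbers were absent: the lowest seen was 28 and the next 45, at list positions 10 and 32. Its highest number per Mb was 2.01 times that of the other autosomes (95% interval 1.77 to 2.28). These intervals cover counting error only.

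**Figure D3:**
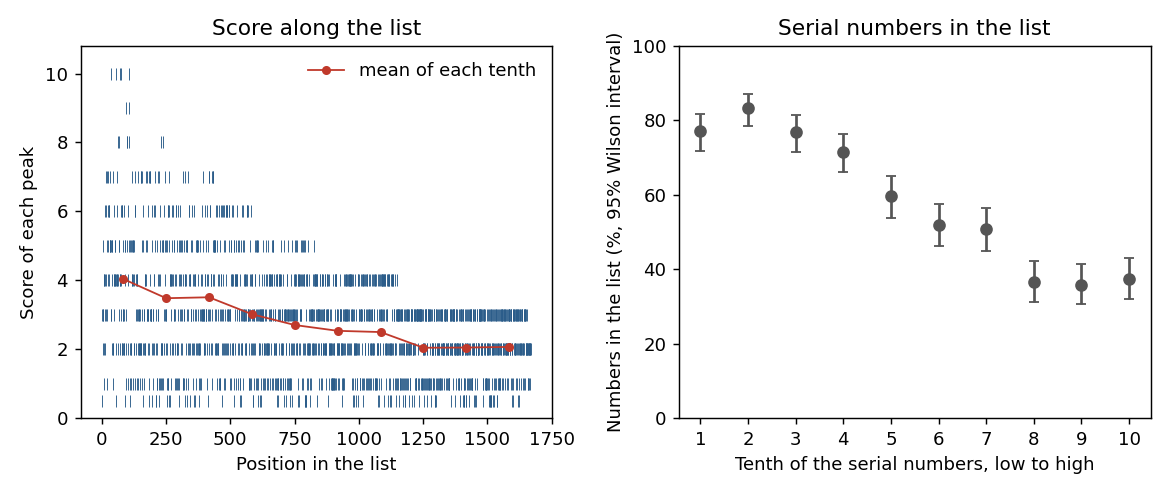
Left, the score of each C/EBPα peak (blue marks, vertical axis) against its position in the list (horizontal axis), with the mean of each successive set of 166 or 167 peaks in red. Right, the percentage of serial numbers seen in the list with 95% Wilson intervals (vertical axis) by successive ranges of the number within each chromosome (horizontal axis), which is 77.1% in the first range, 83.2% in the next and 37.4% in the last.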

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

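The share of peaks with a neighbour stayed above random placement (permutation p = 0.002) under each alternative run. It was 6.59% within 5 kb, 29.3% within 50 kb, 7.38% among the 894 peaks with a score of 3 or more, which replace the 1669 of the whole list, and 10.1% among the first 834 peaks. The meaning of the score is not given and its maximum drops along the list. The filter at a score of 3 or more, here and below, therefore need not keep the stronger peaks. The excess over random placement was 7.82 times at 10 kb, 4.36 times at 50 kb, 14.1 times among the first 834 peaks and 3.59 times when each peak was moved by at most 500 kb. The density on X relative to the autosomes ranged from 0.143 among the first 834 peaks to 0.235 over whole chromosome lengths, and that of chromosome 11 relative to the other autosomes from 1.50 with clusters counted once to 1.87 among the first 834 peaks. Both kept their direction and side of the threshold under each alternative run. The number of chromosomes that differed from their length share was 4 in the whole list, 2 among the first 834 peaks in list order (chromosomes 11 and X), 5 among the 894 peaks (chromosome 9 was added, exact binomial test, adjusted p = 0.028) and 3 with clusters counted once. Among the 894 peaks, a set of similar size to the first 834, chromosomes 2 and 3 were called at 1.44 and 0.553 times their length share (exact binomial test, adjusted p = 0.0037 and 0.0022); the cause of the lost calls was not tested. The higher mean score of peaks with a neighbour, by 0.301, fell to 0.122 within 10 successive parts of the list (permutation p = 0.015 and 0.32), along which both the score and the share with a neighbour fell. Apart from this difference and the calls for chromosomes 2, 3 and 9, each of the 15 alternatives run on a test of a single value kept its direction and side of the threshold. Tests by transcription start site, motif and gene list were not run, for want of a gene table and a genome sequence on mm9. No paired analysis was possible because 1 sample was analysed. The depth is unknown, so how many further sites deeper sequencing would call cannot be given.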

Other observations

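Tests in this part that were chosen only after the result was seen are those of the serial numbers on X, of the score as the ordering quantity and of a single Poisson level; the comparison of low scores was chosen after the upper limit of the score was seen, though before its own value was. Apart from a single X copy, whose test rests on list position, no biological explanation was tested. The design gives no second group with a peak list here.

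The low density of C/EBPα peaks on X was already there in the serial numbers. The highest numbers seen per Mb on X were 0.214 times those of the autosomes (95% interval 0.153 to 0.290). This argues against removal of peaks numbered up to the highest seen as the source of the deficit. Peaks numbered above the highest seen and removed cannot be counted, so removal of such peaks stays open. Peaks on X also stood later in the list, by 191 positions on average (mean position 1023 against 832; two-sided permutation p = 0.044). A single X copy lowering the signal on X, as in cells of male animals, would place peaks on X late, as was seen, if the list runs from stronger to weaker signal. What orders the list is not given in the sources used here, and the sex of the animals is not given in the labels. Under that same order, lower C/EBPα binding on X, or poorer mapping of reads there, would also place its peaks late. The late position does not tell these explanations apart, and all stay open.

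The close spacing of C/EBPα peaks was not accounted for by differences in peak density between regions much wider than 500 kb. Random moves of up to 500 kb to either side partly even out dense regions of about that width, so such regions stay open. The observed 11.02% of peaks with a neighbour within 10 kb lay above the highest of 1000 placements in which each peak moved by at most 500 kb (4.91%). Single bound regions split into several peaks would add neighbours at short range, yet 7.55% of peaks had their nearest neighbour 2 to 10 kb away, above the highest of the same placements (4.25%). Splitting at under 2 kb was therefore not the whole of the excess, but it may be a part. Of the 184 peaks with a neighbour within 10 kb, 126 had their nearest at 2 to 10 kb. The excess over these placements was 3.09 times at 2 to 10 kb, against 3.59 times for all distances within 10 kb. Bound domains wider than 2 kb, and several separate sites around shared genes, remain open, and motif sequences and a gene annotation on mm9 would bear on them.

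The score has an upper limit that drops along the list. Its maximum was 10, 7, 5, 4 and 3 in 5 successive equal parts of the list, and the last peak with a score of 8 stood at position 237, with 7 at 434, with 6 at 582, with 5 at 827 and with 4 at 1150. The score was not the quantity the list is ordered by (rho = -0.35), while a ceiling on the score that tightens down the list, with no other fall, had what it needs: among peaks with a score of at most 3, the mean was 1.96 ± 0.880 (SD, 162 peaks) in the first part and 2.06 ± 0.849 (334 peaks) in the last, a difference of 0.103 (95% bootstrap interval -0.059 to 0.269). For a comparison with Poisson counts, scores of 0.5 were taken as 0, which gave a mean of 2.77. After this change the variance-to-mean ratio over the whole list was 0.964 (Poisson range 0.933 to 1.07). The share at 0.5 was 5.87% (5.15% to 7.49%). The ratio was 0.424 among the last 167 peaks (0.797 to 1.22), which a ceiling would bring about. It was 1.29 among the first 166 (0.795 to 1.23), which a ceiling would not bring about. These ratios hold for the recoded scores only. The ratio among the first 166 peaks argues against a single Poisson level with 0 written as 0.5, while counts whose level varies between peaks stay open. One candidate explanation is that the score counts background tags and that peaks had to exceed them by a set factor. A high score would then not mark strong C/EBPα binding. Fewer high serial numbers were seen (37.4% in the last of 10 ranges against 77.1% in the first and 83.2% in the next). Other filters on peaks could bring this about as well, and nearly all of the lowest numbers on chromosome 11 were absent. The serial numbers therefore do not bear on this explanation in particular. Tag counts per peak would decide it.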
